A study of Mus musculus with 12 samples.

How the data were processed

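RNA from MTΔECad mouse breast cancer cells was sequenced at 6 time points of an adipocyte protocol (0 h, 6 h and days 3, 5, 7 and 10), with 2 libraries each. Per the labels' protocols, total RNA came from 2 independent experiments and libraries were made from 200 ng of RNA with a stranded total RNA kit and sequenced on an Illumina HiSeq. The labels also describe the sequenced RNA as poly-A+. The deposited values are raw counts per gene for the whole series. Reads were aligned with STAR to mm10, per the submitters' processing notes. The version of the aligner, the counting tool and the gene annotation are not given in the sources used here. The table held 17090 Entrez gene identifiers, of which 17045 were matched to symbols with a RefSeq annotation of GRCm38.p6 and 4 with a GENCODE annotation. Another 41 stayed unmatched and kept their identifier. No mitochondrially encoded gene was in the table, so the list of such transcripts, 1 of 33 fixed lists, was not tested.

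Library totals ran from 12820802 to 17570366 counts. Replicate libraries varied more than counting error alone: per time point, chi-square per degree of freedom lay between 4.37 (0 h) and 16.4 (day 3), and the common biological coefficient of variation was 0.0740. Where a group held 0 counts of a gene, the fold change is given as a bound against a floor of 3 counts over the group; where it held 1 to 3 counts, a ratio with a 95% exact counting interval is given, which covers counting error only.

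Counts were fitted with edgeR 4.0.16 in R 4.3.3, in 1 model with a mean per time point over all 12 libraries, which leaves 6 residual degrees of freedom. Factors were by TMM, the filter was filterByExpr (minimum count 10.0, minimum total 15), and 12740 genes were tested after 4350 were removed. Each comparison used the robust quasi-likelihood F test with Benjamini-Hochberg adjustment, called at an adjusted p below 0.05, and 1 joint test covered any difference between time points. P-values measure variation between the 2 independent experiments of each time point, pooled over all 6. Fold changes used a prior count of 0.125. Replicate similarity was measured by correlation and principal components of log2 CPM with a prior count of 2.

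The 9 comparisons, the tests, 33 gene lists with 686 members and the alternatives were chosen before the data were examined. Genes named in the text come from a pool fixed in advance: 38 key genes named in any comparison, the 8 called genes with the largest rise and the 8 with the largest fall per comparison (mean CPM of at least 10.0 in the higher group, no overlap between groups, predicted genes and pseudogenes passed over), and, per list and comparison, the 3 called members with the largest change and the 2 most abundant members. Lists were tested with camera (limma 3.58.1, preset inter-gene correlation 0.01) with Benjamini-Hochberg adjustment over 32 lists in each comparison; member counts were also adjusted over the list alone. Medians of lists were also computed with genes at 0 to 3 counts set to their bound or ratio. Such a gene passed the filter only through times when it was higher, so a change against those times was partly built in. The comparisons of day 5 and day 7 with 0 h and of day 3 with 6 h are given as counts of calls. Apart from day 10 against 0 h, where all 32 lists are given, the lists described in a comparison were picked after their values were seen, and the number that passed is given beside them.

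Alternatives were scaling by median-of-ratios or upper-quartile factors, no filter and a filter at a mean of 1 CPM, DESeq2 1.42.0, a replicate block, a fit of only the 4 libraries compared, a prior count of 1 (another planned value, 0.125, is the default in use and so no alternative), camera with an estimated correlation, fry in place of camera, and each library left out in turn. The steps were tested on simulated data of 12433 genes with 200 changed in day 10 against 0 h. There edgeR recovered 65.7% of genes changed 1.5-fold, 89.6% of those changed 2-fold and 97.0% of those changed 4-fold, and 13 of its 181 calls were unchanged genes. A planted list was called (adjusted p = 1.33e-140; 4.49e-06 with an estimated correlation). The simulated genes varied independently and few were changed, whereas 82.7% of genes were called at day 10 against 0 h in the data. These rates therefore do not cover scaling under so broad a change, nor lists of correlated genes.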

Results

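RNA sequencing counts were collected from MTΔECad cells, a mesenchymal mouse breast cancer cell line, at 6 time points of a protocol that turns them into fat cells: 0 h, 6 h, day 3, day 5, day 7 and day 10. Each time point had 2 libraries, which the labels describe as biological replicates from 2 independent experiments, so 12 libraries entered the main fit. Cells were seeded at 20000 cells per cm2. By the protocol they then received 200 ng/ml of the growth factor BMP2 for 3 days, BMP2 with 2 µM rosiglitazone for 4 days, and rosiglitazone alone for the last 3 days. Rosiglitazone is an agonist of PPARγ, the nuclear receptor that directs fat cell formation. No untreated cells matched in time were among the samples, and time in culture, cell density and treatment change together. Library totals lay between 12820802 and 17570366 counts, and 17090 genes had a count. Values are given as mean ± SD (n = 2) in library-scaled counts (CPM), and log2 fold changes with their standard error (SE). With 2 libraries per time point, p-values rest on a spread pooled over all 6 time points.

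Replicates lay close together: the correlation of log2 CPM between the 2 libraries of a time point was 0.9920 at its lowest (day 3) and 0.9946 at its highest (0 h and 6 h). The first principal component held 78.5% of the variance and ordered the libraries by time from 0 h to day 10, with the 6 h libraries beside those of 0 h. The second component held 13.2% and set day 3 apart from the other times. Of 12740 genes tested, 12060 (94.7%) differed between any time points. The count of genes called with at least a 2-fold change against 0 h was 25 at 6 h, 3464 at day 3, 5363 at day 5, 6046 at day 7 and 6479 at day 10. Among the genes that differed, 3241 (26.9%) had their highest mean at day 10. From 6 h to day 3, 3477 genes were called with at least a 2-fold change, 1775 higher and 1702 lower.

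**Figure D1:**
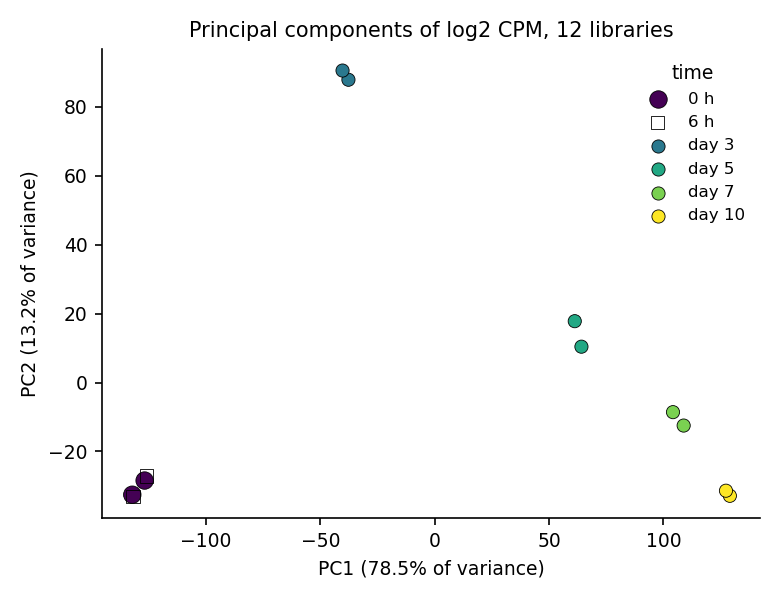
Principal components of log2 CPM over the tested genes, with the first component (78.5% of the variance) on the horizontal axis and the second (13.2%) on the vertical axis; each point is 1 of the 12 libraries, coloured by time. The 6 h libraries (open squares) lie on those of 0 h, and the later times follow along the first component.

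**Figure D2:**
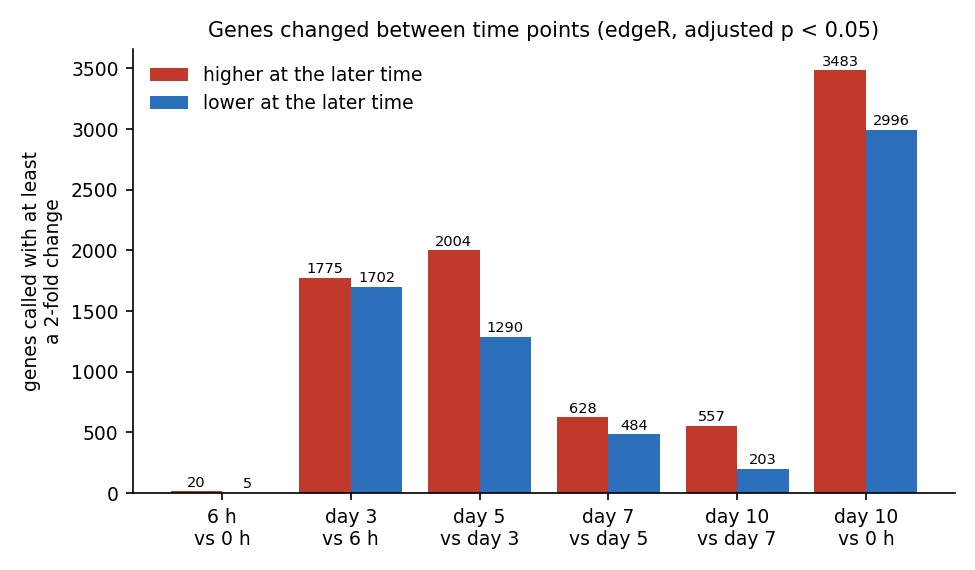
Number of genes called by edgeR with at least a 2-fold change (vertical axis) in each comparison of neighbouring time points and in day 10 against 0 h, split into genes higher and lower at the later time. The bars go from 20 higher and 5 lower at 6 h to 3483 higher and 2996 lower at day 10 against 0 h.

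The comparison of day 10 with 0 h spans the whole protocol. Genes that make and store fat rose. Fabp4, the fatty acid binding protein of fat cells, went from 1.37 ± 0.0708 to 18830.0 ± 576 CPM, a log2 fold change of 13.73 (SE 0.20) with adjusted p = 3.53e-18. Adipoq, which encodes the hormone adiponectin, rose by 12.37 (SE 0.18) to 1113 ± 20.6 CPM, and Plin1, which coats lipid droplets, by 13.07 (SE 0.20). The fatty acid transporter gene Cd36 rose by 13.41 (SE 0.19) and the lipoprotein lipase gene Lpl by 7.29 (SE 0.12). At 0 h Adipoq had 4 and 2 counts, Plin1 1 and 3 and Cd36 5 and 8. Counting error on so few counts is larger than these SEs show, so the 3 fold changes are imprecise. Pparg, the receptor targeted by rosiglitazone, went from 0.135 ± 0.0164 to 339 ± 4.47 CPM (adjusted p = 3.92e-08), Cebpa from 19.0 ± 0.307 to 469.5 ± 36.6 CPM and Cebpb from 31.4 ± 6.01 to 193 ± 29.0 CPM, the last pair being transcription factors of fat cell formation.

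All 21 measured white adipocyte markers rose from 0 h to day 10, over all genes tested and adjusted over the list alone, with a median log2 fold change of 9.85 (camera adjusted p = 8.93e-29). The fixed list held 24 markers, of which 23 had counts and 21 passed the filter. The 6 markers with 0 to 3 counts in a compared group passed only through times when they were higher, so their change was partly built in. Each of the 23 PPAR target genes rose as well, under both adjustments (median 6.82, or 5.61 with the 5 genes at 0 to 3 counts set to their bounds or ratios; adjusted p = 3.54e-28). So did the 18 lipid droplet and lipolysis genes (median 5.77, adjusted p = 9.25e-17) and the 22 fatty acid oxidation genes (median 3.48, adjusted p = 5.46e-25). Their counts were the same adjusted over the list alone. A change was likewise partly built in for the 5 PPAR targets and for 3 lipid droplet genes with 0 to 3 counts in a compared group. With an estimated correlation the camera adjusted p was 0.0267 for white adipocyte markers. It was 0.0426 for PPAR targets, for lipid droplet genes and for fatty acid oxidation genes. Cidec, a lipid droplet protein gene, rose by 13.14 (SE 0.23), and the oxidation enzyme gene Acadm by 5.32 (SE 0.10). Of 23 genes for fatty acid and triglyceride synthesis, 20 rose and 1 fell, and 21 were called when adjusted over the list alone (adjusted p = 1.33e-15; adjusted p = 0.0518 with an estimated correlation). Scd1, which desaturates fatty acids, reached 92890.0 ± 10530.0 CPM and made up 8.22% and 7.20% of all counts in the 2 day 10 libraries. Among 18 adipogenic transcription factors, 14 rose and 1 fell, with 15 called when adjusted over the list alone (median 2.28, adjusted p = 1.53e-05; adjusted p = 0.0518 with an estimated correlation). The 15 inhibitors of adipogenesis went both ways, with 8 risen and 3 fallen and 11 called when adjusted over the list alone (adjusted p = 0.337).

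Some of the genes that rose had no counts at 0 h. Ghrh, the gene for growth hormone-releasing hormone, reached 565 ± 154 CPM, at least 5520-fold higher against a floor of 3 counts over the group. Cidea and Cox8b, used as markers of brown and beige fat, were at least 2290-fold and 2150-fold higher, and the gluconeogenesis enzyme gene Pck1 at least 3050-fold higher. Hsd11b1, which reactivates glucocorticoids, had 2 counts at 0 h and rose by a ratio of 32500 (95% counting interval 8990 to 268000). In the brown and beige list, 7 of 8 measured markers rose, also adjusted over the list alone (median 6.67, or 6.91 with 5 genes at their bounds or ratios; adjusted p = 9.59e-05; adjusted p = 0.0518 with an estimated correlation). The fixed list held 19 markers, of which 15 had counts and 8 passed the filter. The 5 genes with 0 to 3 counts in a compared group passed only through times when they were higher, so a change was partly built in. Ucp1, the uncoupling protein of brown fat, had 1 count in all 12 libraries and was not tested.

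Genes of energy metabolism moved with them. All 41 nuclear genes of oxidative phosphorylation rose by day 10, over all genes tested and adjusted over the list alone (median 1.79, adjusted p = 7.54e-15; adjusted p = 0.138 with an estimated correlation). The cytochrome c gene Cycs went from 9.12 ± 1.54 to 92.7 ± 1.95 CPM and the complex I gene Ndufa1 from 16.2 ± 2.26 to 151 ± 1.97 CPM. In glycolysis, 17 of 19 genes rose under either adjustment, the second adjusted over the list alone (median 1.69, adjusted p = 5.34e-05; adjusted p = 0.343 with an estimated correlation), among them Aldoa by 2.42 (SE 0.093) and Hk2 by 2.93 (SE 0.10). Pdk1 and Pdk4, kinases that restrain the entry of pyruvate into the citric acid cycle, rose by 5.02 (SE 0.19) and 4.87 (SE 0.18). The cholesterol biosynthesis list, with 15 genes risen and 5 fallen of 23 and 20 called when adjusted over the list alone, did not pass (adjusted p = 0.0744), although Insig1 and Hmgcs1 rose by 4.05 (SE 0.36) and 3.14 (SE 0.21). It passed without 0 h replicate 2 (0.0152), 6 h replicate 1 (0.0361) or 6 h replicate 2 (0.0370).

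Cell division genes fell. All 32 mitosis genes (median -6.65, camera adjusted p = 1.87e-41) and all 30 DNA replication genes (median -4.27, adjusted p = 3.54e-28) were lower at day 10, over all genes tested and adjusted over the list alone. With an estimated correlation the camera adjusted p was 0.0406 for mitosis and 0.000478 for DNA replication. Mki67, the proliferation marker, dropped from 998 ± 14.0 to 9.97 ± 1.93 CPM (log2 fold change -6.63 (SE 0.25), adjusted p = 7.41e-09), and Top2a from 1481 ± 35.5 to 15.3 ± 0.938 CPM. The helicase genes Mcm5 and Mcm6 changed by -7.09 (SE 0.15) and -6.32 (SE 0.13), and the cyclin D1 gene Ccnd1 by -4.77 (SE 0.14). Of 14 cell cycle inhibitors 11 rose and 3 fell, all 14 also called when adjusted over the list alone (adjusted p = 0.0224; adjusted p = 0.356 with an estimated correlation). Tob1 and Ccng2 rose by 3.58 (SE 0.11) and 3.46 (SE 0.11), and Cdkn1a, the p21 gene, by 1.34 (SE 0.13). Cdkn1c and Cdkn2a, with 6 and 38 counts over all libraries, were not tested.

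The actin cytoskeleton and growth factor signalling genes fell as well. Of 19 actin and SRF target genes 16 fell and 3 rose, all 19 also called when adjusted over the list alone (median -3.42, adjusted p = 1.99e-07; adjusted p = 0.234 with an estimated correlation). Smooth muscle actin, Acta2, went from 2026 ± 30.4 to 33.9 ± 6.15 CPM and the actin crosslinker Flna from 6123 ± 31.6 to 397 ± 24.6 CPM. Among 21 feedback and target genes of the ERK pathway 16 fell and 3 rose, with 19 called when adjusted over the list alone (median -1.62, adjusted p = 0.000358; adjusted p = 0.112 with an estimated correlation), including Etv4 by -6.77 (SE 0.17) and Epha2 by -4.48 (SE 0.10). In the NF-kB and inflammatory list of 16, 11 genes fell and 2 rose, and 13 were called when adjusted over the list alone (median -2.62, adjusted p = 3.57e-05; adjusted p = 0.0518 with an estimated correlation). The prostaglandin synthase gene Ptgs2 changed by -5.82 (SE 0.11), Csf1 by -5.70 (SE 0.18), and the chemokine gene Ccl2 had 3 counts left at day 10, a ratio of 522 (95% counting interval 178 to 2530).

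A further 3 signalling and invasion lists were lower at day 10, each losing its call with an estimated correlation. WNT targets had 7 genes fallen and 1 risen of 12, with 8 called when adjusted over the list alone (adjusted p = 0.0253; adjusted p = 0.180 with an estimated correlation). For YAP and TEAD targets the counts were 11 fallen and 7 risen of 19, with 18 called when adjusted over the list alone (adjusted p = 0.0451; adjusted p = 0.356 with an estimated correlation). Matrix protease and invasion genes had 13 fallen and 6 risen of 20, and all 20 were called when adjusted over the list alone (adjusted p = 0.0395; adjusted p = 0.230 with an estimated correlation). Ankrd1 changed by -7.19 (SE 0.18) and Axl by -4.12 (SE 0.10), and the urokinase gene Plau and its receptor gene Plaur by -6.65 (SE 0.20) and -6.77 (SE 0.17). The YAP and protease lists also missed the threshold without day 3 replicate 1 (0.0532 and 0.0559), day 3 replicate 2 (0.0532 and 0.0558), day 10 replicate 1 (0.0748 and 0.0930) or day 10 replicate 2 (both 0.0861).

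Lists for cell state and matrix did not pass as groups. The mesenchymal markers had 13 genes fallen and 6 risen of 22, with 20 called when adjusted over the list alone (adjusted p = 0.218). Vim and Cdh2, the vimentin and N-cadherin genes, changed by -1.72 (SE 0.13) and -1.72 (SE 0.073). Zeb2 and Twist1 rose by 0.42 (SE 0.070) and 1.00 (SE 0.12) and the receptor gene Pdgfra by 2.84 (SE 0.22). Zeb2 had 2034 and 2542 counts at 0 h and 2265 and 2703 at day 10, so the size of its rise depends on the scaling of the libraries. Cdh1, which encodes E-cadherin, stayed low, with 0.560 ± 0.169 CPM at 0 h and 0.402 ± 0.189 CPM at day 10 (adjusted p = 0.576), and between 1 and 20 counts in every library. The name of the line, MTΔECad, marks E-cadherin as lost. Low Cdh1 may therefore be a property of the line and says nothing about a change of cell state. Of 11 epithelial markers 4 rose and 5 fell, with 9 called when adjusted over the list alone (adjusted p = 0.492). Krt14 went from 117 ± 17.9 to 664 ± 23.2 CPM, Epcam was at least 57.4-fold higher, and Krt7 changed by -7.44 (SE 0.29). TGF-beta targets had 6 genes risen and 12 fallen of 22, with 18 called when adjusted over the list alone (adjusted p = 0.178). Collagen and matrix genes were split, with 12 risen and 11 fallen of 26 and 23 called when adjusted over the list alone (adjusted p = 0.700). Col6a1 rose by 4.07 (SE 0.36), and Fbln5, with 3 counts at 0 h, by a ratio of 2950 (95% counting interval 1010 to 14300). Among BMP and SMAD1/5 targets 12 rose and 5 fell of 18, with 17 called when adjusted over the list alone (adjusted p = 0.379). Smad6 rose by 3.18 (SE 0.13).

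Interferon response genes were higher at day 10 than at 0 h, with 22 of 23 risen and 1 fallen, all 23 also called when adjusted over the list alone (median 4.27, adjusted p = 6.99e-08; adjusted p = 0.169 with an estimated correlation). Of 26 fixed interferon response genes, 23 passed the filter. Among these, 5 had 0 to 3 counts in a compared group and passed only through times when they were higher, so their change was partly built in. The osteoblast and chondrocyte list, checked because BMP2 also drives bone formation, had 8 genes risen and 2 fallen of 13, with 10 called when adjusted over the list alone (adjusted p = 0.415). Alpl, the alkaline phosphatase gene, had no counts at 0 h and was at least 321-fold higher at 32.5 ± 3.24 CPM. Runx2 had 11.6 ± 2.20 and 11.6 ± 0.00511 CPM (adjusted p = 0.960), and Sp7 had 1 count in all libraries. Markers of other cell types gave no called list. These were leukocyte and macrophage markers (1 risen and 2 fallen of 3 measured, 3 called when adjusted over the list alone, adjusted p = 0.852), endothelial markers (1 risen and 5 fallen of 7, 6 called when adjusted over the list alone, adjusted p = 0.763) and muscle markers (2 risen and 2 fallen of 6, 4 called when adjusted over the list alone, adjusted p = 0.299). Mammary luminal and milk genes had 5 risen and 3 fallen of 9, with 9 called when adjusted over the list alone (median 0.96, yet camera placed the list lower; adjusted p = 0.763). Heat shock and stress genes had 8 risen and 7 fallen of 19, with 15 called when adjusted over the list alone (adjusted p = 0.700). In total 10532 genes were called at day 10, 5448 higher and 5084 lower, of which 6479 changed at least 2-fold.

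**Figure D3:**
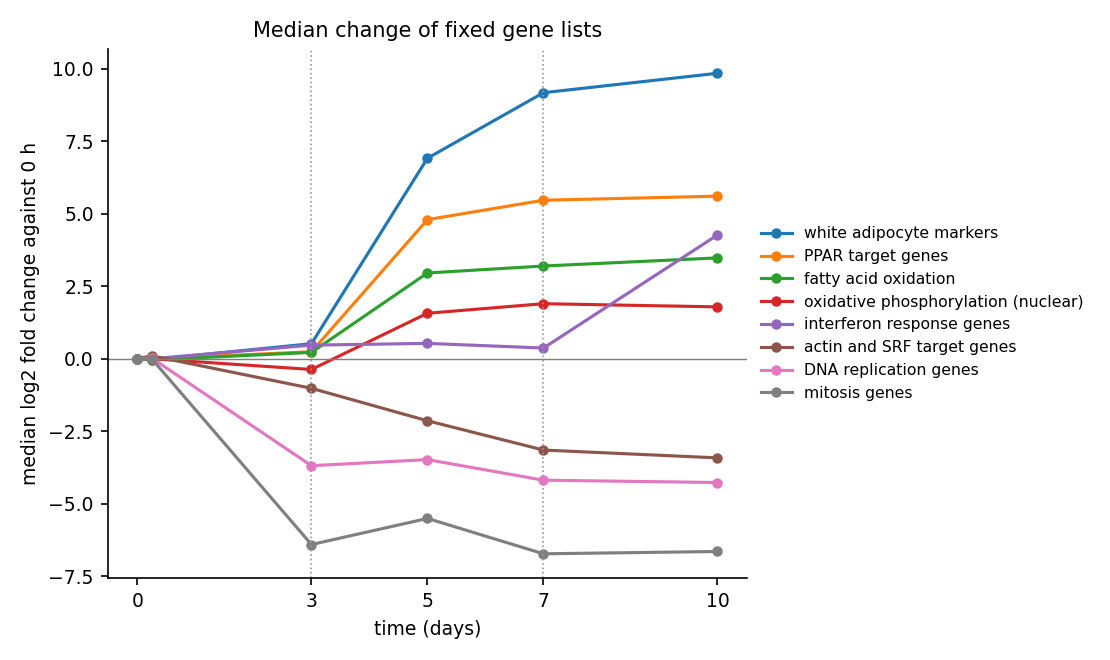
Median log2 fold change against 0 h (vertical axis) of 8 fixed gene lists over time in days (horizontal axis), with genes at 0 to 3 counts in a group set to their bound or counted ratio; dotted lines mark the times at which the medium changed by the protocol, day 3 and day 7. Mitosis genes reach -6.41 at day 3 and white adipocyte markers 9.85 at day 10.

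The comparison of 6 h with 0 h gives the early response, under BMP2 alone by the protocol. Direct targets of BMP signalling rose. Atoh8 went from 12.0 ± 0.314 to 36.2 ± 1.70 CPM (log2 fold change 1.59 (SE 0.11), adjusted p = 9.38e-07), Smad6, an inhibitor of BMP receptors, from 6.54 ± 1.15 to 19.4 ± 1.91 CPM, and the transcriptional inhibitors Id1 and Id2 rose by 1.04 (SE 0.086) and 1.17 (SE 0.086). Smad7, also known as a target of TGF-beta, rose by 1.09 (SE 0.071). The homeobox gene Dlx1, the hyaluronan synthase gene Has2 and the Notch ligand gene Jag1 rose by 1.39 (SE 0.14), 1.26 (SE 0.10) and 1.13 (SE 0.10), and Amigo2 changed by -1.56 (SE 0.17).

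Of the 18 BMP and SMAD1/5 target genes 5 rose over all genes tested and 8 adjusted over the list alone, all of them upward (median 0.59, camera adjusted p = 2.56e-49; 0.000650 with an estimated correlation). Among 22 TGF-beta target genes 7 rose over all genes and 10 adjusted over the list alone (median 0.42, adjusted p = 5.95e-36; 0.0154 with an estimated correlation). Of 32 lists, 4 passed at 6 h, the others being YAP and TEAD targets (1 of 19 risen, 2 adjusted over the list alone; adjusted p = 0.0144; adjusted p = 0.619 with an estimated correlation) and mesenchymal markers (1 of 22 risen, 2 adjusted over the list alone; adjusted p = 0.0144; adjusted p = 0.748 with an estimated correlation). Both lost their calls without 0 h replicate 1 (0.0625 and 0.409) and without 6 h replicate 2 (0.116 and 0.555). Afap1l2 and Tspan15 changed by -0.97 (SE 0.13) and -0.94 (SE 0.12). No member of the white adipocyte list (21 genes, adjusted p = 0.615) or the mitosis list (32 genes, adjusted p = 0.636) was called by edgeR, either over all genes or adjusted over the list alone. Mki67 stood at 998 ± 14.0 and 971 ± 28.4 CPM and Fabp4 at 1.37 ± 0.0708 and 1.28 ± 0.122 CPM. Pparg had 2 and 2 counts at 0 h and 27 and 43 counts at 6 h (0.135 ± 0.0164 and 2.04 ± 0.408 CPM), and edgeR did not call it (adjusted p = 0.319). It was called by DESeq2 (log2 fold change 3.93), and by edgeR with no filter, with the 4 libraries alone, without day 3 replicate 1 and without day 3 replicate 2 (3.86 each). In total 95 genes were called, 68 higher and 27 lower, of which 20 and 5 changed at least 2-fold; 753 had an unadjusted p under 0.05, and DESeq2 called 106. The count was 43 without 0 h replicate 1, 35 without 0 h replicate 2, 53 without 6 h replicate 1 and 40 without 6 h replicate 2, and without 0 h replicate 2 the count with at least a 2-fold change was 12. It was 275 with no filter on low counts and 223 with the 4 libraries fitted alone.

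By day 3, at the end of BMP2 alone, the cells had nearly lost the transcripts of cell division. All 32 mitosis genes fell against 0 h, over all genes and adjusted over the list alone (median -6.41, camera adjusted p = 2.44e-101; 0.00199 with an estimated correlation), as did all 30 DNA replication genes (median -3.69, adjusted p = 1.94e-57; 0.000121 with an estimated correlation). Mki67 went from 998 ± 14.0 to 11.2 ± 4.57 CPM (log2 fold change -6.47 (SE 0.24), adjusted p = 1.81e-08) and Top2a from 1481 ± 35.5 to 33.4 ± 9.77 CPM. The mitosis genes Birc5, Nuf2 and Bub1 changed by -7.92 (SE 0.19), -7.76 (SE 0.18) and -7.71 (SE 0.19), and the nucleotide synthesis genes Rrm1 and Tk1 by -3.70 (SE 0.077) and -7.83 (SE 0.24). The histone genes H3c2 and H2ac12, members of a family with near-identical copies, changed by -8.04 (SE 0.17) and -8.57 (SE 0.27). Of 14 cell cycle inhibitors 10 rose and 4 fell, all 14 also called when adjusted over the list alone (median 0.76, adjusted p = 0.0328; adjusted p = 0.700 with an estimated correlation). Among them Gadd45a rose by 5.17 (SE 0.13).

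Regulators of fat cell formation rose at day 3. Pparg reached 35.7 ± 14.7 CPM (log2 fold change 7.97 (SE 0.57), adjusted p = 3.51e-06), Cebpb 154 ± 8.08 CPM, Cebpd 16.3 ± 1.87 CPM and Cebpa 39.4 ± 5.88 CPM, and Klf15, absent at 0 h, was at least 96.9-fold higher. Of 18 adipogenic transcription factors 15 rose and 2 fell, with 17 called when adjusted over the list alone (median 1.47, adjusted p = 0.000401; adjusted p = 0.258 with an estimated correlation). Among 21 white adipocyte markers 9 rose, and 9 when adjusted over the list alone (median 0.92, or 0.52 with 7 genes at their bounds or ratios; adjusted p = 0.0210; adjusted p = 0.725 with an estimated correlation). Lpl and the lipid droplet gene Plin4 rose by 3.58 (SE 0.11) and 3.49 (SE 0.35), while Fabp4 was at 1.58 ± 0.372 CPM (adjusted p = 0.563) and Plin1 at 0.129 ± 0.00321 CPM (adjusted p = 0.975). Of the BMP targets 10 rose and 4 fell of 18, with 14 called when adjusted over the list alone (adjusted p = 0.0149; adjusted p = 0.381 with an estimated correlation). Id2 rose by 1.84 (SE 0.087) and Smad6 by 2.85 (SE 0.13).

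Of 32 lists, 8 passed at day 3, and 2 of them also with an estimated correlation. Cholesterol biosynthesis genes fell in 18 of 23 cases, also adjusted over the list alone (median -1.18, adjusted p = 0.00112; adjusted p = 0.761 with an estimated correlation). Of the 41 oxidative phosphorylation genes 27 fell and 3 rose, with 30 called when adjusted over the list alone, but the list did not pass (adjusted p = 0.185). Ndufb8 and Uqcrc1 changed by -1.03 (SE 0.12) and -0.93 (SE 0.093). Glycolysis genes fell in 14 of 19 cases and rose in 3, with 17 called when adjusted over the list alone, and the list did not pass (adjusted p = 0.0689). It passed without 0 h replicate 1 (0.0453), day 3 replicate 1 (0.0368), day 7 replicate 1 (0.0400) or day 7 replicate 2 (0.0411). Its members Ldha and Pkm changed by -1.90 (SE 0.089) and -1.41 (SE 0.10). Heat shock and stress genes went both ways, with 9 risen and 9 fallen of 19 and 18 called when adjusted over the list alone (adjusted p = 0.213, and 0.0210 without day 3 replicate 1). Of these Ddit3, Trib3 and Atf3 rose by 4.96 (SE 0.15), 5.59 (SE 0.27) and 4.49 (SE 0.22). Actin and SRF targets fell in 16 of 19 cases and rose in 2, with 18 called when adjusted over the list alone (median -1.02, adjusted p = 0.0328; adjusted p = 0.761 with an estimated correlation; 0.0505 without 0 h replicate 2). Collagen and matrix genes were split, with 11 risen and 11 fallen of 26 and 22 called when adjusted over the list alone (adjusted p = 0.816). Fibronectin, Fn1, went from 1646 ± 434 to 9794 ± 3968 CPM, osteopontin, Spp1, from 1902 ± 249.7 to 8925 ± 303 CPM and the protease inhibitor gene Timp3 from 191 ± 13.9 to 1521 ± 355 CPM. In the other direction, the epithelial keratin gene Krt8 dropped from 553 ± 8.76 to 54.3 ± 13.0 CPM. In total 8682 genes were called, 4220 higher and 4462 lower, of which 3464 changed at least 2-fold. The majority direction depends on scaling: 48.6% of the calls were higher with TMM and 55.3% with upper-quartile factors.

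Between day 3 and day 5, the first days with rosiglitazone, the genes of mature fat cells rose. Plin1 went from 0.129 ± 0.00321 to 687 ± 84.4 CPM (log2 fold change 12.29 (SE 0.20), adjusted p = 1.29e-16), Fabp4 from 1.58 ± 0.372 to 1257 ± 182 CPM and Cd36 from 0.516 ± 0.0786 to 512 ± 44.6 CPM. Plin1 had 2 and 2 counts at day 3, so its fold change is less precise than its SE shows. Adipoq, with 2 counts at day 3, rose by a ratio of 1320 (95% counting interval 366 to 10900). The PPAR target Angptl4, an inhibitor of lipoprotein lipase, rose by 8.70 (SE 0.22), Cebpa by 3.24 (SE 0.12) and Pparg by 2.36 (SE 0.22). Genes with no counts at day 3 were G0s2, an inhibitor of lipolysis (at least 476-fold higher), Thrsp (at least 350-fold) and the glycerol channel gene Aqp7 (at least 256-fold).

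White adipocyte markers rose in 19 of 21 cases, also adjusted over the list alone (median 5.63, camera adjusted p = 7.81e-38), and PPAR targets in 22 of 23, also adjusted over the list alone (median 3.90, adjusted p = 1.62e-38). In these lists 7 and 4 genes had 0 to 3 counts in a compared group and passed the filter only through other times. Fatty acid oxidation (22 of 22, median 2.48, adjusted p = 2.75e-37) and oxidative phosphorylation (41 of 41, median 1.89, adjusted p = 1.21e-38) rose throughout, with the same counts adjusted over the list alone. Acadm, an enzyme of fatty acid oxidation, went from 62.8 ± 7.72 to 1673 ± 124 CPM, and the ATP synthase gene Atp5a1 from 660.2 ± 63.2 to 2634 ± 251 CPM. Synthesis of fatty acids and triglycerides (22 of 23 risen, also adjusted over the list alone, median 2.83, adjusted p = 1.14e-18) and lipid droplet genes (16 of 18 risen and 1 fallen, 17 called when adjusted over the list alone, median 3.72, adjusted p = 1.18e-23) followed, with Agpat2, an enzyme of triglyceride synthesis, up by 5.60 (SE 0.12). These 6 lists kept their calls with an estimated correlation, with adjusted p between 0.0291 and 0.0455. Cholesterol biosynthesis genes turned upward, with 18 risen and 2 fallen of 23 and 20 called when adjusted over the list alone (median 1.73, adjusted p = 0.000142; adjusted p = 0.547 with an estimated correlation). Hmgcs1 rose by 3.32 (SE 0.21).

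ERK pathway genes fell in 16 of 21 cases and rose in 2, with 18 called when adjusted over the list alone (median -1.16, adjusted p = 4.41e-07; 0.0314 with an estimated correlation). Spry1, a feedback inhibitor, went from 102 ± 17.8 to 4.74 ± 0.983 CPM and Etv5 from 27.9 ± 5.90 to 3.25 ± 0.552 CPM. NF-kB and inflammatory genes fell in 10 of 16 cases and rose in 2, with 12 called when adjusted over the list alone (median -1.21, adjusted p = 1.03e-05; 0.0314 with an estimated correlation), including Ptgs2 by -3.67 (SE 0.10) and the cytokine gene Lif by -4.87 (SE 0.28). Fn1, Spp1 and Timp3, which had risen by day 3, changed by -3.03 (SE 0.47), -2.23 (SE 0.15) and -3.47 (SE 0.19). Mki67 rose by 1.41 (SE 0.24) from its level at day 3 (adjusted p = 6.82e-04). Of the mitosis genes, 22 of 32 rose while 2 fell, with 24 called when adjusted over the list alone, but the mitosis list did not pass (median 0.91, adjusted p = 0.0897). It passed without day 3 replicate 1 (0.0101). Of 32 lists, 17 passed from day 3 to day 5, and 8 of them also with an estimated correlation. In total 8275 genes were called, of which 2004 were at least 2-fold higher and 1290 at least 2-fold lower.

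From day 5 to day 7, under BMP2 with rosiglitazone, genes of mature fat cells rose further. Cfd, the secreted protease adipsin, went from 4.28 ± 1.07 to 144 ± 20.8 CPM (log2 fold change 5.08 (SE 0.16), adjusted p = 1.56e-10), Fabp4 rose by 2.87 (SE 0.12), Adipoq by 2.96 (SE 0.094) and Cd36 by 2.39 (SE 0.10). Scd1 rose by 2.70 (SE 0.35) to 42450.0 ± 12120.0 CPM, and Pnpla3, which acts on stored triglycerides, by 4.37 (SE 0.19).

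Of 21 white adipocyte markers 16 rose, also adjusted over the list alone (median 1.24, camera adjusted p = 3.77e-28; 0.0253 with an estimated correlation), and 20 of 23 PPAR targets, also adjusted over the list alone (median 1.10, adjusted p = 3.10e-28; 0.0365 with an estimated correlation). Brown and beige markers rose in 5 of 8 cases, also adjusted over the list alone (median 1.87, adjusted p = 7.60e-09; 0.0365 with an estimated correlation), with Cidea up by 3.65 (SE 0.32) and Clstn3 by 3.21 (SE 0.15). Glycolysis genes rose in 15 of 19 cases, also adjusted over the list alone (median 0.92, adjusted p = 2.54e-12; adjusted p = 0.12 with an estimated correlation), among them the lactate dehydrogenase gene Ldha by 1.13 (SE 0.087). Actin and SRF targets fell in 16 of 19 cases over all genes, with 17 called when adjusted over the list alone (median -0.87, adjusted p = 4.04e-11; adjusted p = 0.147 with an estimated correlation). Acta2 went from 252 ± 13.9 to 58.2 ± 23.1 CPM. Mitosis genes fell in 26 of 32 cases and rose in 1, with 27 called when adjusted over the list alone (median -1.22, adjusted p = 2.44e-10; adjusted p = 0.152 with an estimated correlation). DNA replication genes fell in 19 of 30 while 2 rose, with 23 called when adjusted over the list alone (median -0.67, adjusted p = 1.48e-07; 0.0253 with an estimated correlation). Mki67 returned to 8.66 ± 2.07 CPM, the neutrophil lipocalin gene Lcn2 changed by -3.23 (SE 0.26) and the stem cell antigen gene Ly6a by -2.35 (SE 0.094). Pparg and Cebpa, at 247 ± 10.8 and 438 ± 27.7 CPM on day 7, were not called (adjusted p = 0.139 and 0.0913). Pparg was called by DESeq2 (log2 fold change 0.45), with no filter (0.44), with the 4 libraries alone (0.43), without day 3 replicate 1 and without day 3 replicate 2 (0.42 each), and Cebpa with no filter (0.25), without day 3 replicate 1 or day 3 replicate 2 (0.23 each) and without day 5 replicate 1 (0.40). Of 32 lists, 17 passed from day 5 to day 7, and 4 of them also with an estimated correlation. In total 4815 genes were called, of which 628 were at least 2-fold higher and 484 at least 2-fold lower; without day 7 replicate 1, 3128 were called.

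**Figure D4:**
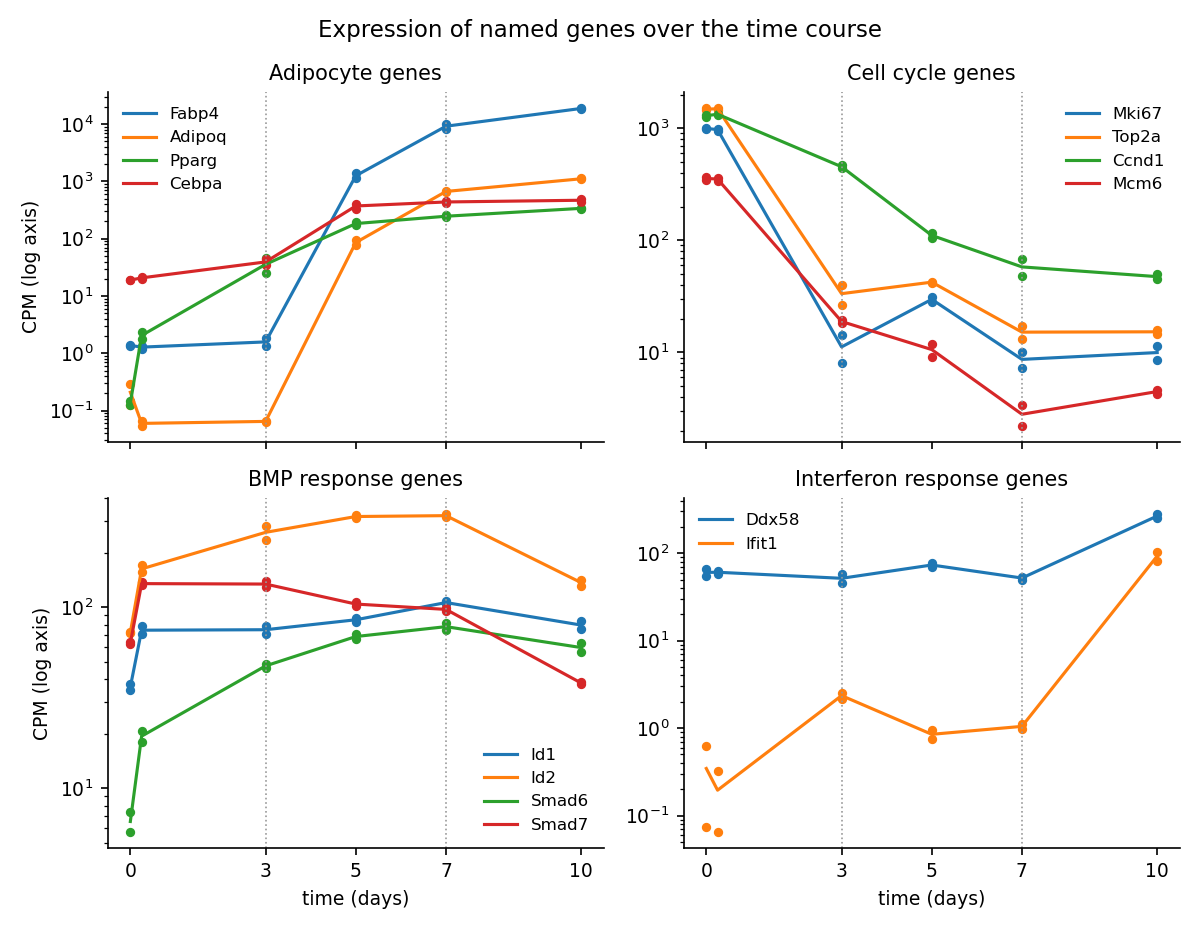
CPM on a log axis (vertical) against time in days (horizontal) for adipocyte, cell cycle, BMP response and interferon response genes; points are the single libraries, lines join the means of the 2 libraries, and dotted lines mark day 3 and day 7, when the medium changed by the protocol. From day 3 to day 5 Fabp4 changes by 9.63 (SE 0.18), and from day 7 to day 10 Id2 changes by -1.23 (SE 0.084) and Ifit1 by 6.46 (SE 0.25).

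From day 7 to day 10, after BMP2 was removed by the protocol, interferon response genes rose. All 23 measured members were called higher, over all genes and adjusted over the list alone (median 3.98, camera adjusted p = 8.33e-103; 0.00487 with an estimated correlation). Ifit1 went from 1.05 ± 0.0849 to 92.8 ± 16.4 CPM (log2 fold change 6.46 (SE 0.25), adjusted p = 2.17e-10) and Ifi44 from 0.131 ± 0.0106 to 11.8 ± 1.02 CPM. Oasl2, with 3 counts at day 7, rose by a ratio of 200 (95% counting interval 67.9 to 971), and the abundant member Ddx58, which encodes an RNA sensor, rose by 2.35 (SE 0.11). Ifnk, which encodes interferon kappa, went from 0.166 ± 0.0596 to 12.2 ± 1.28 CPM (adjusted p = 2.06e-07). The leukocyte and macrophage list was not called, with 1 fallen of 3 measured members, also adjusted over the list alone (adjusted p = 0.724), and Cd14 stood at 4.95 ± 0.245 and 6.09 ± 0.382 CPM (adjusted p = 0.319).

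BMP target genes fell. Of 18 measured members 11 fell and 2 rose, with 14 called when adjusted over the list alone (median -0.49, adjusted p = 9.48e-08; adjusted p = 0.0657 with an estimated correlation). Id2 went from 320.5 ± 9.11 to 136 ± 6.84 CPM (adjusted p = 2.10e-08), Id3 and Id4 changed by -0.96 (SE 0.13) and -1.69 (SE 0.24) and Hey1 by -2.68 (SE 0.22). Dlx1, which had risen at 6 h, changed by -2.60 (SE 0.20), and Smad7 by -1.35 (SE 0.075). TGF-beta targets fell in 8 of 22 cases and rose in 3, with 12 called when adjusted over the list alone (median -0.39, adjusted p = 0.00721; adjusted p = 0.612 with an estimated correlation). Krt15, a keratin of basal epithelia, fell from 257 ± 24.8 to 32.0 ± 6.67 CPM.

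White adipocyte markers rose further in 13 of 21 cases, and in 14 adjusted over the list alone (median 0.46, adjusted p = 7.83e-07; adjusted p = 0.509 with an estimated correlation). Cfd and Fabp4 rose by 2.04 (SE 0.12) and 1.03 (SE 0.11), and Dgat2, the last enzyme of triglyceride synthesis, by 1.61 (SE 0.093), while Plin1 was at 1189 ± 55.4 and 1226 ± 104 CPM (adjusted p = 0.751). The glucose transporter gene Slc2a1 and the glycolytic regulator Pfkfb3 rose by 1.77 (SE 0.14) and 2.35 (SE 0.15). Atf4 and Slc7a1, a stress transcription factor and an arginine transporter, changed by -1.06 (SE 0.089) and -2.15 (SE 0.20). Of 32 lists, 11 passed from day 7 to day 10, and 1 of them also with an estimated correlation. In total 3615 genes were called, of which 557 were at least 2-fold higher and 203 at least 2-fold lower. The count of calls was 2143 without day 7 replicate 2, 2351 without day 10 replicate 1 and 2370 without day 10 replicate 2.

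The genes behind these comparisons lie on several chromosomes of GRCm38.p6, the assembly that matches the mm10 build of the counts. Pparg spans chromosome 6:115360879-115490404 (Entrez 19016), Fabp4 chromosome 3:10204342-10208616 (Entrez 11770), Adipoq chromosome 16:23146536-23157968 (Entrez 11450), Mki67 chromosome 7:135689784-135716450 (Entrez 17345), Acta2 chromosome 19:34240336-34255585 (Entrez 11475), Smad6 chromosome 9:63953076-64022085 (Entrez 17130), Id2 chromosome 12:25093799-25096092 (Entrez 15902), Ifnk chromosome 4:35152055-35154019 (Entrez 387510) and Ghrh chromosome 2:157329496-157348725 (Entrez 14601), each interval being the annotated gene from its first to its last exon.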

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

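No test in this part was chosen after the result was seen, but the genes named in every comparison were taken from their pool, and the lists shown outside day 10 against 0 h were picked, with their values known. For day 10 against 0 h, calls with camera were lost with an estimated correlation for adipogenic transcription factors, fatty acid synthesis, brown and beige markers and NF-kB genes (each 0.0518), oxidative phosphorylation (0.138), glycolysis (0.343), ERK genes (0.112), WNT targets (0.180), YAP targets (0.356), proteases (0.230), SRF targets (0.234), cell cycle inhibitors (0.356) and interferon response genes (0.169). At 6 h this held for YAP targets (0.619) and mesenchymal markers (0.748), and at day 3 against 0 h for adipogenic transcription factors (0.258), white adipocyte markers (0.725), cholesterol biosynthesis (0.761), BMP targets (0.381), cell cycle inhibitors (0.700) and SRF targets (0.761), and from day 3 to day 5 for cholesterol biosynthesis (0.547). From day 5 to day 7 it held for glycolysis (0.12), SRF targets (0.147) and mitosis (0.152), and from day 7 to day 10 for BMP targets (0.0657), white adipocyte markers (0.509) and TGF-beta targets (0.612). The cause was not tested.

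With fry, lists not called by camera passed: at day 10 against 0 h inhibitors of adipogenesis (0.000278), cholesterol biosynthesis (0.000581), BMP targets (2.36e-05), TGF-beta targets (0.000559), mesenchymal (0.00136) and epithelial markers (0.000351), osteoblast markers (0.000100), heat shock genes (0.0113), leukocyte (0.0365), endothelial (0.000493) and muscle markers (3.33e-06), at day 3 against 0 h oxidative phosphorylation (0.00129), glycolysis (0.000726), heat shock (0.00957) and collagen genes (0.0384), and from day 3 to day 5 mitosis (0.00364). At 6 h YAP targets (0.480) and mesenchymal markers (0.646) lost their calls with fry. Fry asks whether genes moved at all, not whether they moved more than other genes. With no filter, cholesterol biosynthesis at day 10 against 0 h (0.0176), oxidative phosphorylation (0.000754) and glycolysis (0.00817) at day 3 against 0 h and mitosis from day 3 to day 5 (0.000624) passed, and WNT targets (0.0799), YAP targets (0.161) and proteases (0.110) at day 10 against 0 h, cell cycle inhibitors at day 3 against 0 h (0.0563) and TGF-beta targets from day 7 to day 10 (0.0712) did not; the cause was not tested. The 6 h count was 275 with no filter (48 with at least a 2-fold change) and 223 with only the 4 libraries compared.

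Leaving out 1 library at a time, where a lone library is assumed to vary like the other groups, gave 35 to 141 calls at 6 h (12 to 30.0 with at least a 2-fold change), 3128 to 5154 from day 5 to day 7 and 2143 to 3998 from day 7 to day 10. The adjusted p ranged from 0.0152 to 0.0997 for cholesterol biosynthesis, from 0.0181 to 0.0861 for YAP targets and from 0.00935 to 0.0930 for proteases at day 10 against 0 h, and from 0.0101 to 0.230 for mitosis from day 3 to day 5. At 6 h it ranged from 0.000360 to 0.116 for YAP targets and from 6.18e-05 to 0.555 for mesenchymal markers, and at day 3 against 0 h from 0.00195 to 0.0505 for SRF targets, from 0.0368 to 0.0749 for glycolysis and from 0.0210 to 0.391 for heat shock genes. With all 12 libraries or only the 4 compared, all counts of calls other than those of 6 h against 0 h stayed within 1.25 times the reported value. The share of calls that were higher moved by up to 7.1 percentage points with upper-quartile scaling (day 3 against 6 h). Replicate numbers were not taken to pair the samples: over 15 pairs of time points the correlation of deviations ran from -0.091 to 0.193, the highest being that of 0 h with 6 h. With the replicate block, 6 h gave 105 calls and day 10 against 0 h 10576, and glycolysis at day 3 against 0 h passed (0.0374), with no other list changing its call. Among the genes named with a test, Pparg at 6 h and Pparg and Cebpa from day 5 to day 7 changed their calls, as given in the report. Of 161 such results, 160.0 had a value under the stricter filter and 159 with only the 4 libraries.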

Other observations

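The families of gene symbols below, the interferon genes searched and the 3 tests on the interferon response (Ifnk, leukocyte markers, single libraries) were chosen after the result was seen. Gene families defined by shared symbol stems (218 with at least 8 tested members) were compared with all other genes by a hypergeometric test, adjusted over 3924 tests. The test takes the members of a family as independent, so its p-values are too small where members move together. Of all genes, 27.4% were called higher and 23.5% lower with at least a 2-fold change at day 10 against 0 h. Some Ndufb genes are also in the oxidative phosphorylation list. From 0 h to day 10, 13 of 16 measured Pex genes, which build peroxisomes, were called higher with at least a 2-fold change (median log2 fold change 2.55, adjusted p = 0.00103), as were 10 of 10 Ndufb genes of mitochondrial complex I. In the other direction, 15 of 20 Nup genes of the nuclear pore (median -2.02, adjusted p = 0.000213) and 7 of 8 Cct genes of the chaperonin that folds actin and tubulin (adjusted p = 0.0133) were lower with at least such a change. The small nucleolar RNA genes (Snord, 19 of 30, adjusted p = 0.000424) and their host genes (Snhg, 11 of 14, adjusted p = 0.00169) were lower as well. The Gbp genes, interferon-induced GTPases, were at least 2-fold higher at day 10 than at day 7 in 9 of 10 cases, against 4.4% of all genes (adjusted p = 7.01e-09).

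A gene identifier without a matched symbol, Entrez 100861531, held 2.09% and 2.02% of all counts in the 0 h libraries, 2.67% and 1.98% at 6 h, 0.48% and 0.95% at day 3, and 0.52% and 0.25% at day 10. What this identifier names is not given in the sources used here.

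The rise of interferon response genes between day 7 and day 10 was weighed against other causes. The values argue against a sizeable share of leukocytes at day 10. Ptprc had 0 counts in both day 10 libraries and Lyz2 had 2 and 0, with at most 1 and 3 counts in any library. The summed CPM of 11 leukocyte markers was 11.6 and 12.1 at day 7 and 10.8 and 9.2 at day 10 (-0.25 on the log2 scale). Most of that sum was Cd68 and Cd14, present from 0 h on, which could hide a small share, so a small share stays open. A single deviating library is excluded, because 23 of 23 members were above both day 7 libraries in both day 10 libraries. The hypothesis of an interferon made by the cells fits, with Ifnk changed by 6.16 from 5 counts at day 7 to 297 at day 10, but the protein was not measured. BMP2 was removed by the protocol in the same interval, and whether its removal or time alone could account for the rise was not tested.

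Ribosomal protein genes, a set defined from the same tables after the values were seen, were lower at day 10 than at 0 h in 69 of 76 cases (median -1.18), of which 52 fell at least 2-fold. Of random lists matched in expression and transcript length, 0.0% had a median as low, and 95% of their medians lay between 0.13 and 1.14. These values argue against a trend with expression or length as the whole cause. They do not exclude it, because ribosomal protein genes were left out of the pool and the closeness of the match was not checked. Genes were also drawn independently, so the lists vary less than lists of genes that move together. Library totals alone gave -1.57 from mean CPM (-1.53 in the edgeR fit), which decides nothing, since the scaling factors fix that shift for all genes alike, so the part of scaling in the size of the fall stays open. Reads shared with pseudogenes may matter and were not tested, and cells that stop dividing could also lower these transcripts, which the samples cannot separate from time in culture.

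The protocadherin beta genes, cell adhesion genes in a cluster on chromosome 18 (37294840 to 37521419, GRCm38.p6), were higher in 17 of 18 cases at day 10 than at 0 h (median 3.16) and already at day 3 (17, median 2.52). A gain of the wider region does not account for this: 78 genes within 5 Mb, protocadherins left out, had a median of -0.05, with 31 higher and 33 lower. A gain limited to protocadherin genes could not be seen this way and stays open. The rise was not limited to the beta genes. At day 5 against 0 h, 12 of 12 Pcdhga genes, another protocadherin family, were called higher with at least a 2-fold change (median 1.26). That family did not pass at day 10 against 0 h. Of matched random lists 0.17% had a median as high, but the family was picked from 218 and 0.37 of such families would lie as high by chance, so a trend with expression or length stays open. The members are similar in sequence, and reads shared between them could spread 1 gene's rise over the others. Their log2 fold changes had an SD of 1.19 against a median SE of 0.38. Shared reads could also give unequal changes, because each member's change depends on its own level at 0 h. The spread therefore decides nothing, and shared reads stay open.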
